A study of Homo sapiens with 3 samples.

How the data were processed

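Each of 3 samples was a 2-colour Agilent array on which Cy3-labelled RNA of the H1 ES cell line was hybridised together with Cy5-labelled RNA of mix2, per the labels. The spots were quantified with Agilent Feature Extraction version 9.5.3.1, per the file headers, on an array design of 41000 probes whose positions are given on the hg17 build. All 3 arrays lay on 1 slide and shared 1 scan, per the file headers, so slide and scan batches hold 1 group only and could not be tested. The deposited scanner files hold mean spot and median background signals as intensity on a linear scale, per the file headers. They also hold the authors' Feature Extraction log ratio as log10 of Cy5 over Cy3, after background subtraction, detrending and a LOWESS dye normalization with smoothing 0.25, per the file headers. The deposited series table holds log2 values, one per probe and array, with no stated scale, centring or direction. Set against the scanner log ratios, they equalled log2 of Cy3 over Cy5 for 89.3%, 92.6% and 94.2% of the probes of replicates 1, 2 and 3 within a tolerance of 1e-04, with column medians of 0.12, 0.12 and -0.01, so they are ES cells over mix2 and not centred. The rest differed by up to 0.496 log2 units, and the step that made this difference is not given in the sources used here.

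The analysis started from the mean and background signals. The background was corrected with normexp and an offset of 50, and each array was normalized by loess (span 0.3) with control spots and outlier spots at weight 0, in limma version 3.58.1 under R version 4.3.3 (data.table version 1.17.8, figures in Python version 3.11.15 with matplotlib version 3.10.9). The offset shrinks ratios of dim probes toward 0. The loess step assumes that most genes at a given intensity have balanced ratios, which is a strong assumption between cell types this different, so median centring was run beside it. Control spots were then left out, outlier spots (80 to 89 of 43376 non-control spots per array) were set to missing and the spots of a probe averaged. No non-control spot was saturated (0 on each array). The sign was taken from the dye labels and turned to ES cells over mix2. A probe was tested where the same channel was well above background on at least 2 of the 3 arrays, which left 34259 probes. A linear model with an intercept only was fitted with lmFit and eBayes, and the ratio tested against 0, since mix2 is a control RNA on every array. P-values were adjusted by Benjamini-Hochberg over the tested probes. A gene was called at an adjusted p under 0.05 and a log2 ratio of at least 1 in size. The bound on the ratio was set because a dye bias of a probe cannot be told apart from its ratio without swapped dyes.

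A gene is represented by its tested probe with the highest mean intensity. Of 6087 genes with several tested probes, the probes of 4517 all had the same call, and 44 genes had probes called in opposite directions. Of the 41000 probes, 23434 were named through their RefSeq accession in a table of the GRCh38.p14 assembly, 5008 kept the gene name of the file, and 12558 had neither and were tested without a gene name. Names of that table were used without its coordinates, and probe positions are those of the files. No exon annotation of the hg17 build was used here. Genes of the Y chromosome and XIST are not reported, nor is CD24, whose probe the files place on the Y chromosome. A ratio of a gene not well above background in the dimmer channel on any array was turned into a bound per channel after loess and Aquantile, from the higher of the probe's own signal and the lowest signal well above background.

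Before the data were examined, 28 gene lists with 626 genes were fixed for pluripotency, cell identity, cell cycle, immune, signalling and metabolic genes, and for markers of other cell types. Of these genes 593 were tested, and TRIM71, TET1 and TET3 had no probe under these names. The shift of each list was tested with camera and a preset correlation of 0.01, adjusted over the lists. With an estimated correlation, which 3 arrays estimate poorly, none of the 14 calls held (0 lists). That setting also rests on the few residual degrees of freedom of 3 arrays, so few lists could pass whatever their correlation. Class I antigen presentation had an estimated correlation of -0.02, under the preset one, yet its camera adjusted p rose from 2.3e-05 to 0.375. For such a list, losing a call there says little on whether it shifted. The estimated correlation was far above the preset one for pluripotency factors and ES cell markers (0.55) and for epithelial junctions and keratins (0.51). The camera adjusted p-values of those lists thus depend on the preset correlation. Genes to be named were chosen by a rule fixed before the data were examined. It takes the 12 called genes with the largest log2 ratio per direction among those measured in both channels on all arrays, the 6 per direction with the largest bound, up to 4 called members of each list per direction, and 16 fixed genes; clone and open reading frame names were left out. It gave 179 genes. Those not called are named only as fixed genes or members of a list, and members of the list of secreted proteins and of gene families named under the other observations were chosen after values were seen.

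The steps from the model to the calls were tested on simulated data made from the spread of the real probes. In the comparison of ES cells with mix2, 60 of 61 changed probes were called at a true log2 ratio of 1.25, 64 of 64 at 2 and 75 of 75 at 3. There were 0 false calls among 34059 unchanged probes, of which 90 passed the adjusted p alone. With so small a spread between arrays, a false call past the 2-fold bound was nearly out of reach. Few probes were changed, with random signs, so the loess assumption was not tested at the breadth of the real difference. The alternatives tried were no background correction, an offset of 10, median centring without loess, Agilent's log ratio, Aquantile, the series table, no filter and a stricter filter on dim probes, outlier spots kept, the median over the probes of a gene, an intensity trend in eBayes, no bound on the ratio, limma's treat, leaving out each replicate, and for lists an estimated correlation and fry. Agilent's spike-in controls lay near the negative controls in these files and were not used.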

Results

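The gene expression of H1 cells, a line of human embryonic stem (ES) cells also known as WA01, was set against that of human fibroblasts on 3 Agilent microarrays. The ES cells were grown on irradiated mouse embryonic fibroblasts, which serve as feeder cells, in a medium that held basic fibroblast growth factor at 100 ng/ml and serum replacement at 20%. The fibroblast RNA, named mix2, was a mixture of RNA from CCD-1079Sk, a skin fibroblast line, and IMR90, a lung fibroblast line, both grown in medium with 10% serum. Each array carried RNA of 1 ES cell replicate in the Cy3 channel and mix2 in the Cy5 channel, and no array had the dyes swapped. Of 41000 probes, between 73.6% and 83.4% per array were well above background in the ES cell channel and between 74.3% and 81.7% in the mix2 channel. The number of arrays limits the precision of every value. Log2 ratios are given as ES cells over mix2, so positive values are higher in ES cells, each with its moderated standard error over 3 arrays. The value of a gene is that of its brightest probe, and the error does not cover differences between its probes. Where the probes of a named gene lay more than 1 log2 unit apart, their span is given. The question that the design addresses is which genes are expressed differently in ES cells and in these fibroblasts.

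H1 cells and mix2 differed over a large part of the measured genes. Of 16972 genes tested, 3595 were at least 2-fold higher in ES cells and 3563 at least 2-fold lower at an adjusted p under 0.05 (limma, ratio tested against 0), together 42.2%. The extremes were larger on the fibroblast side, with 799 genes at least 3 log2 units lower and 514 at least 3 log2 units higher. The split of 50.2% higher among the called genes depended on the scaling. When each array was centred on its median without loess, 4520 genes were higher and 2895 lower, a higher share of 61.0%, and the median log2 ratio of all genes moved from -0.04 to 0.18. The test leaves out the spread of mix2, a single control RNA. Nothing in the labels says that the 3 ES cell replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The arrays correlated at a Pearson r of 0.998 in each pair across probes, which are not independent replicates, and pairs differed by a median of 0.03 to 0.04 log2 units per probe.

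Genes that define the pluripotent state were higher in H1 cells as a group. Of 29 tested pluripotency factors and ES cell markers, 26 were called higher and 0 lower, with a median log2 ratio of 3.57 (camera adjusted p = 3.2e-06; adjusted p = 0.4997 with an estimated correlation). NANOG, a homeobox factor of the pluripotency network, had a log2 ratio of 6.37 ± 0.02, an 82.6-fold difference, at a probe on chromosome 12 from 7839754 to 7839813 of the hg17 build. ZFP42, a zinc finger factor also known as REX1, reached 6.21 ± 0.05, and the RNA-binding LIN28B and LIN28A reached 6.01 ± 0.03 (4.30 at the other LIN28B probe) and 4.67 ± 0.03. The DNA methyltransferase DNMT3B was 40.1-fold higher (5.33 ± 0.03). POU5F1, which encodes OCT4, was 4.84-fold higher (2.28 ± 0.03) at its brightest probe, on chromosome 6 from 31240157 to 31240216, while its 4 probes spanned log2 ratios from 2.28 to 4.14. Transcripts of POU5F1 pseudogenes share sequence with it, so its value is uncertain. SOX2 was higher by 2.91 ± 0.04 at its brightest probe and by 8.60 ± 0.03 at its other one. The 3 members not called were ZSCAN10 (0.12 ± 0.02), UTF1 (-0.10 ± 0.02) and FOXD3 (-0.94 ± 0.01).

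The other reprogramming factors and the surface antigens did not all go the same way. MYC, a growth-promoting transcription factor, had a log2 ratio of 1.13 ± 0.01 at its brightest probe and -0.17 ± 0.01 at its other one, and was not called when the median of its probes was tested (0.48). KLF4, a zinc finger factor, was lower in ES cells by a narrow margin (-1.01 ± 0.01) and was not called after median centring (-0.65) or with Agilent's own log ratios (-0.96). Of 10 tested surface antigens, 6 were called higher, 2 lower and the list as a whole did not pass (median 1.76, camera adjusted p = 0.205). EPCAM, an epithelial adhesion molecule, was 157-fold higher (7.29 ± 0.03), PODXL, the core protein of ES cell keratan sulphate antigens, reached 5.75 ± 0.04 and PROM1 4.56 ± 0.03. THY1, a surface protein of fibroblasts that ES cells also carry, was 9.38-fold lower (-3.23 ± 0.01), and CD9 was lower at -1.15 ± 0.01, a call that median centring ended (-0.82).

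**Figure D1:**
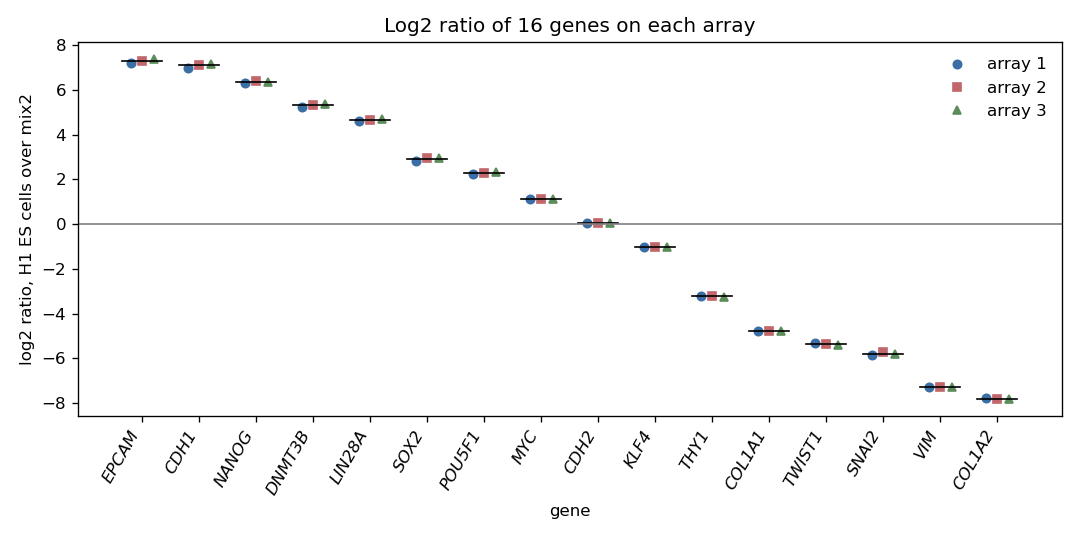
Log2 ratio of ES cells over mix2 (vertical axis) for 16 genes named before the data were examined (horizontal axis), with 1 symbol per array and a black line at the mean of the 3 arrays. The symbols of a gene lie close together, from means above 7 for EPCAM and CDH1 to means below -7 for VIM and COL1A2, with CDH2 near 0 (0.04).

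Epithelial genes were higher and mesenchymal genes lower in H1 cells. Of 29 tested genes of epithelial junctions and keratins, 26 were called higher and 0 lower (median 2.64, camera adjusted p = 1.9e-07; adjusted p = 0.4997 with an estimated correlation). CDH1, which encodes E-cadherin, was 137-fold higher (7.10 ± 0.04) at a probe on chromosome 16 from 67426715 to 67426774. Of 22 mesenchymal regulators and contractile genes, 20 were called lower and 0 higher (median -4.87, camera adjusted p = 4.2e-06; adjusted p = 0.375 with an estimated correlation). VIM, the intermediate filament vimentin, was 156-fold lower (-7.28 ± 0.01). The transcription factors SNAI2 and TWIST1 were 55.7-fold (-5.80 ± 0.03) and 40.8-fold (-5.35 ± 0.02) lower at their brightest probes, while their probes spanned -5.80 to -2.20 and -5.35 to -3.31. NT5E, which encodes CD73, stood at -7.86 ± 0.03 with probes from -7.86 to -6.07. CDH2, which encodes N-cadherin, was not called (0.04 ± 0.01), nor was SNAI1 (-0.67 ± 0.01).

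Genes of the fibroblast extracellular matrix showed the largest shift of any list. Of 34 tested members, 33 were called lower in H1 cells and 0 higher (median -5.59, camera adjusted p = 2.1e-09; adjusted p = 0.375 with an estimated correlation). The small proteoglycans DCN and LUM were 468-fold (-8.87 ± 0.02) and 460-fold (-8.84 ± 0.01) lower, COL12A1 was 376-fold lower (-8.56 ± 0.01) and COL1A2, a chain of type I collagen, 224-fold lower (-7.81 ± 0.02). COL1A1, the other chain of type I collagen, was lower by a smaller factor of 27.5 (-4.78 ± 0.01). ELN, which encodes elastin, was not called at its brightest probe (-0.76 ± 0.02), although its 4 probes reached -3.01. The 2 probes of COL12A1 spanned -8.56 to -6.15 and those of COL1A2 -7.81 to -5.48. For 32 members well above background in both channels on all arrays, the ES cell signal was a median of 2.08% of the mix2 signal. It ranged from 0.214% for DCN to 59.0% for ELN. Whether RNA of the mouse feeder cells added to the ES cell signal was not tested, as these cells have no probes of their own. Of 18 integrins, 11 were called lower and 3 higher (median -2.27), and the list did not pass (camera adjusted p = 0.0563), although it did after median centring (median -1.98, adjusted p = 0.0119), with no background correction (-2.24, adjusted p = 0.0492), and with Agilent's log ratio and the series table (-2.39, adjusted p = 0.0423 in both). ITGA11, a collagen receptor subunit, stood at -5.34 ± 0.02 and ITGA6, a laminin receptor subunit, at 1.83 ± 0.01.

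**Figure D2:**
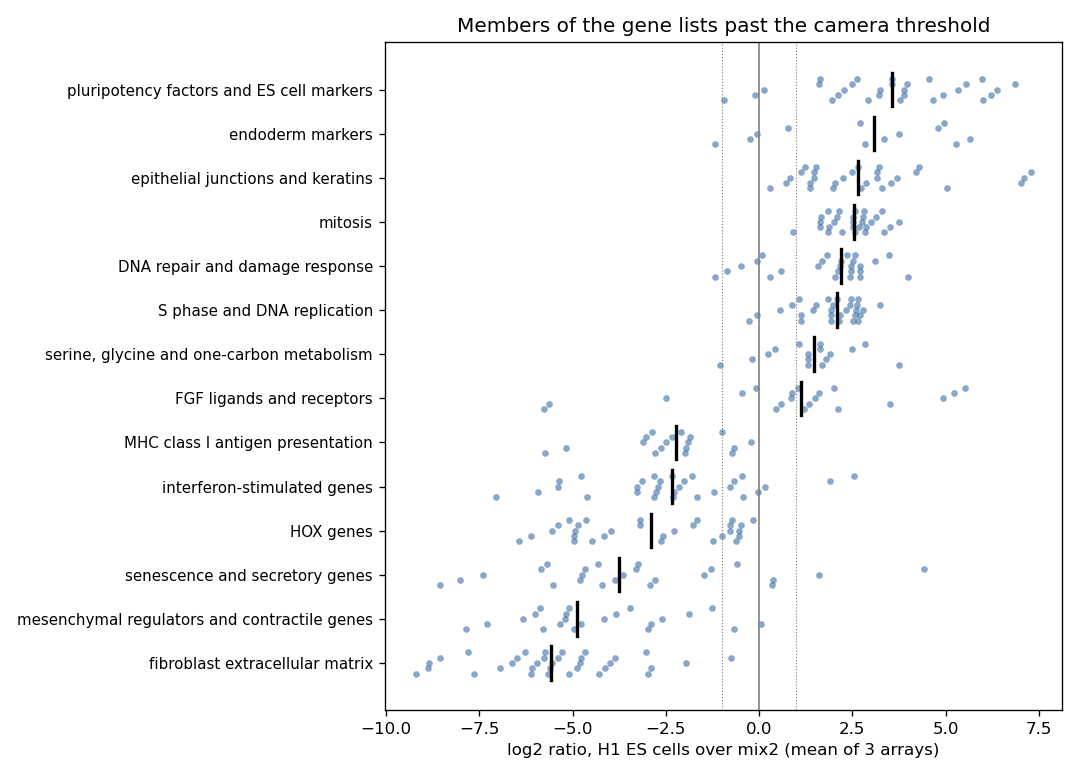
Log2 ratio of ES cells over mix2 (horizontal axis, mean of 3 arrays) of each tested member (points) of the 14 gene lists past the camera threshold, with the list median as a black bar and dotted lines at the 2-fold bounds. List medians run from -5.59 for the fibroblast extracellular matrix to 3.57 for pluripotency factors and ES cell markers.

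Genes of DNA replication, mitosis and DNA repair were higher in H1 cells. In the S phase list, 25 of 29 tested genes were called higher and 0 lower (median 2.09, camera adjusted p = 2.0e-06; adjusted p = 0.375 with an estimated correlation), among them the replication factor MCM10 at 3.25 ± 0.02 and the clamp loader subunit RFC4 at 2.78 ± 0.01. In the mitosis list, 27 of 28 were called higher and 0 lower (median 2.54, camera adjusted p = 6.9e-08; adjusted p = 0.375 with an estimated correlation). The spindle checkpoint genes BUB1B, BUB1 and TTK had log2 ratios of 3.75 ± 0.01, 3.49 ± 0.02 and 3.34 ± 0.02. In the DNA repair list, 19 of 26 were called higher and 1 lower (median 2.19, camera adjusted p = 2.8e-04; adjusted p = 0.375 with an estimated correlation), with the helicase BLM 15.9-fold higher and FANCD2, of the Fanconi pathway, at 3.49 ± 0.01 (probes from 1.56 to 3.49). ATM (-0.48 ± 0.01) and ATR (0.07 ± 0.01), the damage kinases, were not called. Of 16 genes of serine, glycine and one-carbon metabolism, 12 were called higher and 1 lower (median 1.46, camera adjusted p = 0.00191; adjusted p = 0.375 with an estimated correlation). GLDC, the glycine decarboxylase, was highest among them at 3.74 ± 0.01.

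Senescence-associated, antigen presentation and interferon-stimulated genes were lower in H1 cells. Of 24 tested senescence and secretory genes, 19 were called lower and 2 higher (median -3.75, camera adjusted p = 5.0e-04; adjusted p = 0.375 with an estimated correlation). IGFBP7, a secreted binding protein, was 380-fold lower (-8.57 ± 0.02), and the collagenase MMP1 stood at -8.03 ± 0.02. The 2 members higher in ES cells were LMNB1, a nuclear lamin (4.41 ± 0.03), and CDKN1C (1.60 ± 0.01). Of 18 genes of class I antigen presentation, 15 were called lower and 0 higher (median -2.22, camera adjusted p = 2.3e-05; adjusted p = 0.375 with an estimated correlation). B2M, the shared light chain, stood at -5.18 ± 0.01 at its brighter probe and at -1.67 at its other one, and the trimming peptidase ERAP2 at -5.75 ± 0.04, while HLA-C, whose probes can read related HLA genes, stood at -3.10 ± 0.02 with probes from -3.10 to -1.90. Of 30 interferon-stimulated genes, 22 were called lower and 2 higher (median -2.33, camera adjusted p = 5.3e-05; adjusted p = 0.375 with an estimated correlation). IFIT2 stood at -7.05 ± 0.07 and IFI6 at -5.40 ± 0.02, and the 2 higher members were HERC5 (2.55 ± 0.02) and BST2 (1.91 ± 0.02).

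HOX genes were lower in H1 cells, while genes of growth factor pathways went both ways. Of 30 tested HOX genes, which mark positions along the body axis, 22 were called lower in H1 cells and 0 higher (median -2.91, camera adjusted p = 3.2e-06; adjusted p = 0.375 with an estimated correlation). HOXB5 stood at -5.39 ± 0.02, while HOXB7 was not called at its brighter probe (-0.54 ± 0.02), its other one being at -2.39. Of 20 genes of FGF ligands, receptors and feedback regulators, 11 were called higher and 3 lower (median 1.11, camera adjusted p = 0.0446; adjusted p = 0.551 with an estimated correlation), and median centring ended the call of the list (median 1.42, adjusted p = 0.0607). FGF13, FGFR2 and FGFR3 had log2 ratios of 5.51 ± 0.02, 5.21 ± 0.04 and 4.93 ± 0.03, against -5.77 ± 0.02 for FGF7, a fibroblast-secreted ligand. The probes of FGFR2 spanned 2.78 to 5.21 and those of FGFR3 1.26 to 4.93. FGF2, the factor supplied in the ES cell medium, was not called (-0.07 ± 0.01). The WNT receptors and antagonists held 7 higher and 9 lower genes of 24 (camera adjusted p = 0.954). Their median was 0.10 and their mean -0.58, with the receptor FZD5 at 4.67 ± 0.02 and the ligand WNT5A at -6.94 ± 0.01. The TGF-beta, activin and BMP list held 7 higher and 12 lower genes of 34 (median -0.28, camera adjusted p = 0.275), from BMP7 at 3.31 ± 0.04 (2.21 at its other probe) to TGFBI at -8.34 ± 0.02 and the BMP antagonist GREM1 at -8.32 ± 0.01.

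Of the markers of other cell types, those of endoderm were higher in H1 cells, a difference that stands beside the higher pluripotency genes in the same RNA. Of 12 tested endoderm markers, 8 were called higher and 1 lower (median 3.09, camera adjusted p = 0.0389; adjusted p = 0.4997 with an estimated correlation). The list was no longer past the threshold when only probes well above background in both channels on all arrays were tested (median 2.77, adjusted p = 0.0993). The serum proteins TTR and AFP had log2 ratios of 5.27 ± 0.04 and 4.97 ± 0.03, the chemokine receptor CXCR4 5.65 ± 0.05 and the forkhead factor FOXA2 4.80 ± 0.02, with FOXA2 probes from 1.28 to 4.80. SOX17 was called lower at its brightest probe (-1.18 ± 0.02), but its other probe gave 5.23 ± 0.03 and the median of both was 2.02, so its direction is not settled. Among 11 mesoderm markers 2 were called higher and 5 lower (median -0.54, camera adjusted p = 0.275), among 12 neuroectoderm markers 5 higher and 0 lower (median 0.85, adjusted p = 0.205), and among 12 trophoblast markers 3 higher and 3 lower (median 0.23, adjusted p = 0.773). Among mesoderm markers, the receptor KDR stood at 2.38 ± 0.03 and the forkhead factor FOXF1 at -8.17 ± 0.04. The neural factor PAX6 stood at 2.65 ± 0.02, and the trophoblast factors GATA3 and GATA2 at 2.87 ± 0.02 and -2.21 ± 0.01. Of 11 endothelial and blood markers 1 was higher and 2 lower (median -0.18, adjusted p = 0.507), and of 9 keratinocyte and melanocyte markers 1 was higher and 2 lower (median -0.31, adjusted p = 0.235).

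Several lists held members in both directions or few calls. Of 27 genes of DNA methylation and Polycomb complexes, 9 were called higher and 5 lower (camera adjusted p = 0.794), with a median of -0.07 and a mean of 0.48. JARID2, a Polycomb cofactor, stood at 4.23 ± 0.02 and the de novo methyltransferase DNMT3A at 3.01 ± 0.02 (1.62 at its other probe), while CBX6 and BMI1 stood at -2.76 ± 0.01 and -1.84 ± 0.01. Of 21 imprinted genes, 8 were called higher and 7 lower (camera adjusted p = 0.899), with a median of 0.47 and a mean of -0.35. SNRPN stood at 2.43 ± 0.01 and the non-coding RNA MEG3 at -6.00 ± 0.01 at the brightest of 4 probes spanning -6.00 to -1.81. Of 21 glycolysis genes, 3 were called higher and 3 lower (median 0.11, adjusted p = 0.463), with the glucose transporter SLC2A3 at 2.28 ± 0.02 (1.26 at its other probe). None of 29 ribosomal protein genes was called higher and 5 were called lower (median -0.38, adjusted p = 0.205), a list that passed as lower after median centring (median -0.79, adjusted p = 5.4e-05). Of 15 widely used reference genes, 1 was called higher and 4 lower (median -0.34, adjusted p = 0.275), with HPRT1 (1.32 ± 0.01) on the higher side and GAPDH (-1.13 ± 0.01), ACTB (-2.80 ± 0.02, probes from -2.80 to -1.27) and B2M among those on the lower side. In all 28 lists the counts of called members adjusted over the list alone equalled those adjusted over all tested probes. Only 682 of 16972 tested genes missed the adjusted p threshold, so the 2-fold bound set nearly all calls. That equality was thus nearly fixed in advance.

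Among genes measured in both channels on all arrays, each taken at its brightest probe, the largest ratio on the ES cell side was that of MYCN, a transcription factor of the MYC family, which was 253-fold higher (7.99 ± 0.03) at a probe on chromosome 2 from 16037365 to 16037424. A second MYCN probe gave -0.03. Other large ratios, besides EPCAM and CDH1, were those of the neuropeptide gene NMU (6.77 ± 0.03) and CXADR, a junction protein and virus receptor (6.60 ± 0.05 at the brightest of 3 probes spanning 6.18 to 6.60). On the fibroblast side CEMIP, which takes part in hyaluronan breakdown, was lowest at -11.59 ± 0.03 at a probe on chromosome 15 from 79030858 to 79030917, and its 3 probes spanned -11.59 to -3.71. GPNMB, a membrane glycoprotein, stood at -8.99 ± 0.03 at its brightest probe and at -3.56 at another, the protease CTSK at -8.75 ± 0.02 and the galectin LGALS1 at -8.59 ± 0.05. PSG8 (-8.47 ± 0.03) and PSG6 (-8.34 ± 0.03) belong to the pregnancy-specific glycoproteins, whose members are near-identical, so their single values are uncertain, and the other probe of PSG8 stood at -4.76.

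For 549 genes mix2 was not well above background on any array, and for 339 genes the ES cells were not, so those ratios are lower bounds, taken per channel and open to dye bias because no dyes were swapped. GATM, an enzyme of creatine synthesis, was at least 76.0-fold higher in ES cells, the sulfotransferase gene HS6ST2 at least 42.2-fold, the fibrinogen chain FGB at least 39.0-fold and the epithelial factor GRHL2 at least 32.7-fold. In mix2, FAP, the fibroblast activation protein, was at least 429-fold higher than in ES cells, the inflammatory caspase CASP1 at least 185-fold and the interferon-induced GBP1 at least 67.9-fold. The adjusted p of these genes was at most 7.6e-07. A further 1557 genes had a channel well above background on some arrays only, which makes their ratios less certain. Of the genes named above, these were ERAP2, IFIT2, FGF7, AFP, CXCR4 and PAX6. The probes of ERAP2 spanned log2 ratios from -5.75 to -1.42, those of IFIT2 from -7.05 to -3.53 and those of FGF7 from -5.77 to -3.20.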

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

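The tests of dye bias and of signal near background were chosen only after the results were seen; those of one shared ES cell RNA and of endoderm-like cells were set before their values were known. Outside the gene probes, 9 kinds of control probe other than corner spots lay above the negative controls (mean plus 3 SD) in both channels on all 3 arrays. Of these, 8 carry names of 1 series of 10 Agilent control probes. None of the 10 kinds of E1A spike-in probe was above that level in both channels on all arrays, and what the 9 kinds detect was not tested.

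The breadth of the difference, with 42.2% of the tested genes called, was weighed against dye bias. Across 6087 genes with several probes, the log2 ratios of the 2 brightest probes of a gene correlated at a Pearson r of 0.822 (bootstrap 95% interval over genes 0.807 to 0.836), and 93.9% of the genes whose brightest probe differed at least 2-fold had a second probe of the same sign. That argues against a bias specific to each probe as the whole cause. A dye bias shared by all probes of a transcript cannot be told apart from a real ratio, since the number of dye-swapped arrays was 0. The difference between ES cells and fibroblasts that the design names remains open as the biological explanation.

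The arrays repeated each other closely, and the arrays may have carried one ES cell RNA. Over 27938 probes measured in both channels on all arrays, the median variance across arrays in the ES cell channel was 0.807 times that in the mix2 channel (bootstrap 95% interval 0.788 to 0.827), so the ES cell replicates varied no more than the shared control. Among the 16082 probes whose channels lay within 2-fold of each other, the ratio was 0.906. Spots of one probe on one array varied alike in both channels (Cy3 over Cy5 variance ratio 1.01). That value is within arrays, so it cannot show whether the dyes differ in their spread between arrays. At 264 probes with 10 spots each, the log2 ratio had a median SD between arrays of 0.0122, against 0.0117 predicted from the spots alone. The median variance was 1.08 times the predicted one. A variance over 3 arrays has a median below its expected value, more so than one pooled over many spots. The ratio therefore understates the spread between arrays, and it cannot show how little the ES cell replicates added beyond the spots. Cultures that were separate but very alike would give the same values, so the origin of the replicates stays open. The adjusted p-values are best read as a statement about these arrays.

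Endoderm markers were higher in H1 cells. The 8 called markers had an ES cell signal a median of 5.23 log2 units above the 99th percentile of probes not above background. The smallest margin was 3.07 (lowest array of each), so the signal of these 8 was not near background. They had been called higher, with log2 ratios of 2.71 or more, which nearly fixed that outcome in advance. It is thus no independent test. A separate list of 21 secreted proteins of yolk sac and liver, written after the endoderm markers were seen but before its own values were, and sharing 0 genes with the other lists, was tested for endoderm-like cells in the cultures. Of its 19 tested members, 100% were called higher, against 21.2% of all genes. Their median log2 ratio of 2.88 lay above all 10000 random lists matched on intensity. APOB stood at 4.94 ± 0.03 and APOA2 at 3.64 ± 0.04. The random lists were not matched on being low in fibroblasts. For FGG, APOC3, CP and SERPINC1, mix2 was well above background on 0 arrays, so they were tested only through a bright ES cell signal. Their calls thus leaned higher in advance, while most other members were well above background in both channels. The values leave room for some endoderm-like cells among the H1 cells, but expression of these genes by the ES cells themselves was not tested. The labels name no sort that would remove such cells. The share of such cells was not estimated.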

How the results depend on the processing

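No added alternative entered the counts of genes and lists; gene families and the secreted list were chosen after the results were seen. Of 179 named genes, 164 kept their call and direction under every alternative run for them, and 0 genes were called in the opposite direction under any alternative except the median over probes (5 genes). The 3595 higher and 3563 lower genes became 7919 and 8371 with no bound on the ratio, by construction, since that bound was all that was removed. Leaving out each replicate gave 3577 to 3602 higher and 3554 to 3571 lower genes, and 8 lists higher and 6 lower each time. Agilent's log ratio gave 4501 and 3683 genes, the stricter filter on dim probes 2976 and 3146, and limma's treat 3372 and 3391. Aquantile leaves ratios as they are by construction. With an estimated correlation, a setting that 3 arrays leave little power to pass, 0 lists were higher and 0 lower. With fry, which tests a list against 0 and not against other genes, 12 lists were higher and 15 lower. SOX17 reversed to 2.02 with the median of its probes, which disagree. Some lists not called in the main setting changed the direction of their test, though not the sign of their median. With fry, the test of imprinted genes turned from higher to lower (median 0.47, adjusted p = 2.0e-05). It did so too with median centring (0.82), Agilent's log ratio and the series table (0.60 in both). Trophoblast markers with fry (0.23) and glycolysis with median centring (0.0834) also turned from higher to lower. WNT receptors and antagonists turned from lower to higher without the filter (0.19), without replicate 1 (0.11) and without replicate 3 (0.0799). The cause was not tested. Median centring ended the call of 9 named genes and Agilent's log ratio of 3. The log2 ratio of each array already pairs both RNAs, and no further pairing was possible with 1 group. The planned slide or scan batch was not run, as 1 slide and 1 scan hold all arrays. Signal over background limits 549 genes in mix2 and 339 in ES cells to bounds.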

Other observations

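The families below were grouped by the letters of their symbols and tested with camera only after the lists had been seen. Of 276 families with at least 8 tested genes, 8 passed as higher and 10 as lower in H1 cells. Of those that passed, 4 were made up mostly of genes in the fixed lists. The olfactory receptors (OR) passed as lower (median -0.27, camera adjusted p = 0.0336), although 2 of 72 were called higher, 4 lower and 66 not called. A pass can thus rest on a small shift with few called genes. With an estimated correlation, a setting that 3 arrays leave little power to pass, 0 passed (adjusted p = 0.782 at the lowest). Nucleoporins, the proteins of the nuclear pore, were higher, with 15 of 22 called higher and 0 lower (median 1.41, adjusted p = 9.9e-04), led by NUP210 (3.31 ± 0.05, 0.86 at its other probe), NUP35 (2.77 ± 0.02) and NUP205 (2.27 ± 0.01). Of 34 DDX RNA helicases, 10 were called higher and 1 lower (median 0.63, adjusted p = 0.00596), with DDX21 at 1.86 ± 0.01 and the interferon-induced DDX60 at -2.55 ± 0.02. Of 432 ZNF zinc finger genes, 138 were called higher and 41 lower (median 0.55, adjusted p = 0.00596), from ZNF649 at 4.14 ± 0.02 to ZNF503 at -4.66 ± 0.02. These 3 families kept their direction and passed under all 12 alternatives run for them. The SR splicing factors, with 6 of 12 called higher and 0 lower (median 1.00, adjusted p = 0.0461), passed under 7 of the 12, with SRSF7 at 2.08 ± 0.01 and SRSF3 at 2.07 ± 0.01.

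On the lower side, all 9 tested pregnancy-specific glycoproteins were called lower (median -7.61, adjusted p = 0.0264), although their probes can read each other's transcripts. Of 12 metallothionein genes, which bind metals, 8 were called lower and 1 higher (median -2.22, adjusted p = 0.0498), with MT2A at -5.24 ± 0.02 and MT1F, in the other direction, at 3.13 ± 0.03; the family passed under 7 of 12 alternatives, and its members share sequence. Of 9 TCEAL genes 7 were lower and 0 higher (median -1.88, adjusted p = 0.0357), with TCEAL6 at -2.87 ± 0.01. The glycoproteins and the TCEAL genes no longer passed under 1 of 12 alternatives, which kept only probes above background in both channels on all arrays (adjusted p = 0.135 and 0.0749). All 3 families kept their direction under the 12. Median log2 ratios of the 22 autosomes, by the probes' positions in the files, ran from -0.18 to 0.12, and 0 of them passed camera after adjustment, with 0 at an unadjusted p under 0.05.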
